A study of Homo sapiens with 32 samples.

How the data were processed

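Poly-A RNA from U2OS cells, an osteosarcoma line, was sequenced in 32 libraries. Per the labels, the cells had wild-type p53 (WT), no p53 (KO), 1 allele with the A347D change (HET) or both alleles with it (HOM), and received DMSO or 20 µM etoposide (ETO), a topoisomerase II poison, for 24 h. Each of the 8 groups held 4 libraries from separate plates, which the series counts as biological replicates. The labels do not say how many edited lines each genotype had; 1 line per genotype was assumed, in which case genotype and line cannot be separated, and every p-value measures the spread between plates.

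Per the labels, the authors quantified reads with kallisto against GRCh38 (hg38) and normalized and tested the counts with DESeq2; the versions were not given in the sources used here. The deposited matrix held variance-stabilized values on a log2-like scale for 35587 gene symbols, with a floor of 4.43. The authors also deposited result tables for 6 contrasts, with a mean normalized signal per gene, log2 fold changes, p-values and adjusted p-values. The matrix values were inverted to normalized counts, whose mean over the libraries equalled the deposited mean signal within a relative difference of 4.4e-14. Undoing the library scaling gave counts that were whole within 0.01 in 100.0% of the values in each library. The mean was above 0 for 30613 genes and 0 for 4974 genes. Positions and transcript lengths came from GENCODE release 29 on GRCh38: 35373 symbols matched by gene name, 102 by an older symbol and 112 not at all. The strand used in counting was not stated, so overlapping antisense genes cannot be told apart.

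Recovered totals were 18.25 to 24.19 M counts per library, apart from replicate 2 of HET with etoposide at 8.05 M. A gene with 3 counts in a library, the floor used here for a group at 0, had 2.301 to 6.371 normalized counts, depending on the library. This floor covers counting error only. No pair of replicates was a duplicate: the chi-square over degrees of freedom between 2 replicates of a group was 1.89 to 254.38.

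Genes with at least 10 normalized counts in at least 4 libraries were tested, which left 16824. The test was limma's moderated test with a trend, on log2 of the normalized count plus 1, with all 32 libraries and 1 mean per group in a single fit. P-values were two-sided and adjusted with the Benjamini-Hochberg method over the genes of each contrast. A gene passed at an adjusted p under 0.05 and a fold change of at least 1.5. There were 16 contrasts: the etoposide response within each genotype, 4 genotype differences in DMSO, the same 4 in etoposide, and 4 differences between responses. Where list members are counted as responding more or less, or higher or lower, the sign of this difference is meant, also for genes that fell. Fold changes are given on the log2 scale with the standard error (SE) of the fit, and levels as mean and standard deviation (SD) of normalized counts over 4 libraries per group. The SE rests on 1 spread per gene, pooled over all 8 groups. It is therefore not the spread of the compared groups. It is too small where HOM in DMSO varied more, and can be too large in contrasts that leave HOM in DMSO out. The design, the tests, the gene lists, the naming rule and most alternatives were fixed before the data were examined.

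Genes are named by a rule: in each 2-group contrast, the 5 largest rises and 5 largest falls among passing genes with a mean of at least 50 in 1 of the groups and no overlap between the replicates, and 3 of each for a difference between responses. CDKN1A, MDM2, BBC3, BAX and GDF15 were always reported, and each list could name up to 2 rising and 2 falling members. Where a group held 0 counts, the fold is a bound against 3 counts per library; where it held 1 to 3 counts in all, levels are given and no fold. A few genes that the rule names are not reported here.

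There were 22 lists: p53 targets, the BCL2 family, G2 and mitosis genes, S-phase and replication genes, homologous recombination and Fanconi genes, replication histones, NF-kB targets and cytokines, immediate-early and AP-1 genes, interferon-stimulated genes, cholesterol synthesis, the ATF4 stress response, the endoplasmic reticulum unfolded protein response, NRF2 targets, glycolysis and hypoxia genes, nuclear oxidative phosphorylation genes, mtDNA-encoded genes, mitochondrial chaperones and proteases, mitochondrial outer membrane and dynamics genes, cytosolic ribosomal proteins, matrix and osteoblast genes, epithelial markers and blood cell markers. Each was counted and tested with camera, a competitive test in limma, at a preset correlation of 0.01, and again with an estimated correlation. The 352 list tests were adjusted together with the Benjamini-Hochberg method. Poly-A selection captures replication histone transcripts poorly. TOMM40 and SP7, each on a list, were absent from the matrix and not analysed here.

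Alternatives were a pseudocount of 5 in place of 1, no filter on low values, a stricter filter of 50 (13569 genes), quantile normalization, rescaling by the median of ratios, fits on the compared groups alone, the replicate number as a block, each library left out in turn, and the authors' deposited tables. Added after the data were seen were total-count scaling, leaving out HOM DMSO libraries 2 to 4, array weights, voom on the recovered counts, the variance-stabilized values as deposited, and removal of the GC content and transcript length trend of each library. A quasi-likelihood test on recovered counts had been planned and was not run; voom took its place. In simulated data with 16824 genes, changes of 1.5-fold, 2-fold and 4-fold passed for 47.8%, 100% and 100% of changed genes in HOM against KO with etoposide, for 49.3%, 97% and 100% in the WT response, and for 25.4%, 94% and 97% in the difference between the HOM and WT responses. The unchanged genes that passed numbered 0, 4 and 2 in these runs. The changed genes had a mean of at least 50 normalized counts. All groups were given the gene's median spread over the 8 groups, so that the larger spread of HOM in DMSO was left out. The work used R 4.3.3, limma 3.58.1, version 1.17.8 of data.table, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.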

Results

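Transcript levels were measured in 32 libraries from U2OS cells of 4 p53 genotypes, each with DMSO or 20 µM etoposide for 24 h and with 4 plates per group. Etoposide traps topoisomerase II on DNA and leaves double-strand breaks, to which p53 responds as a transcription factor. A347D lies in the p53 tetramerization domain, and the series title describes the mutant as a dimer former that promotes mitochondrial cell death without transactivation. The comparisons ask which etoposide-responsive genes need p53, and how the heterozygous and homozygous mutant cells stand between wild-type and p53-null cells. Recovered totals were 18.25 to 24.19 M counts per library, apart from 8.05 M in replicate 2 of HET with etoposide.

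**Figure D1:**
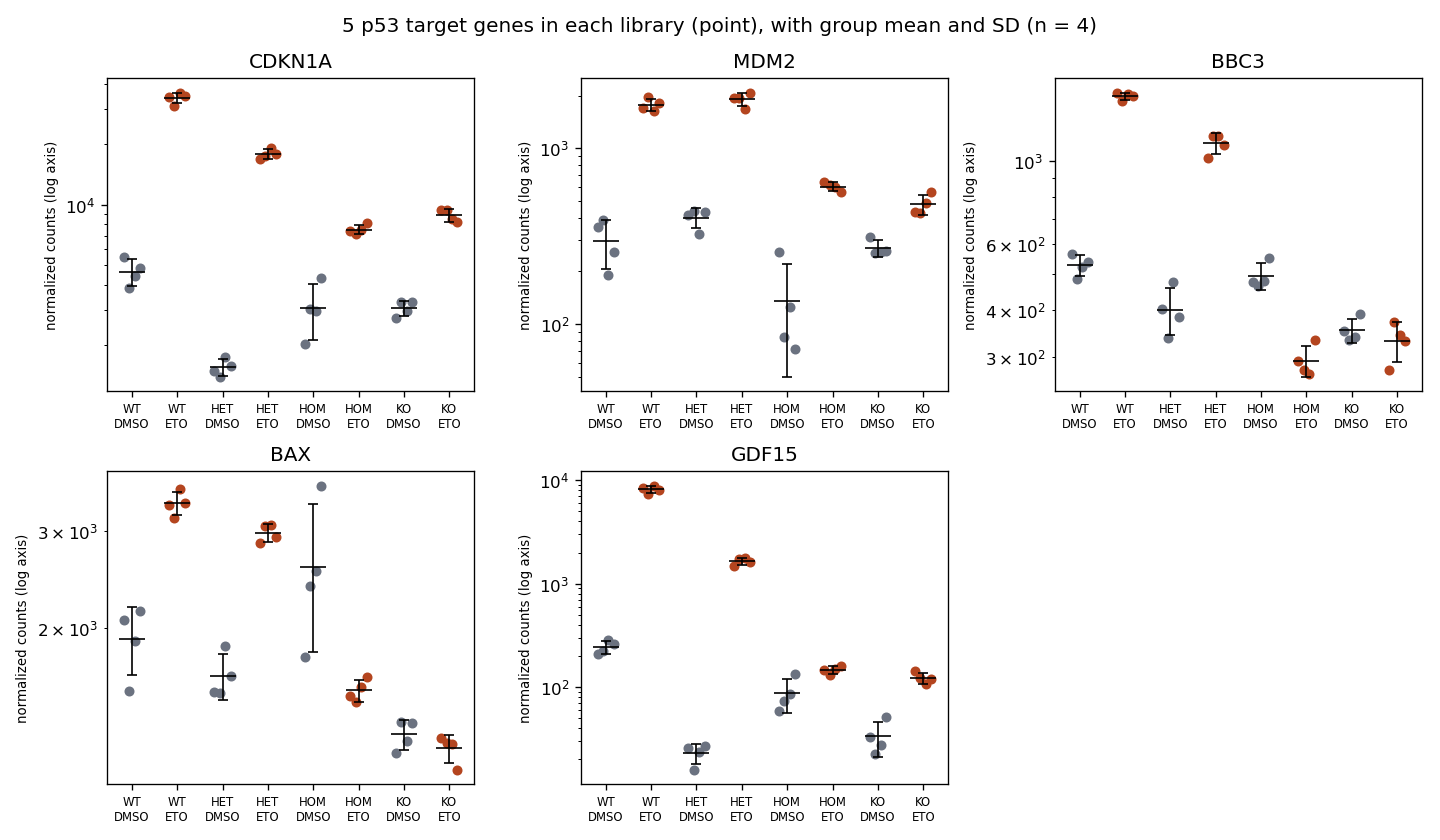
Normalized counts (log axis) of the p53 target genes CDKN1A, MDM2, BBC3, BAX and GDF15 in each library (point), by genotype and treatment, with the group mean and SD (n = 4). CDKN1A with etoposide averaged 34110 in WT and 17880 in HET, against 7526 in HOM and 8875 in KO.

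Replicate 1 of HOM in DMSO resembled the other DMSO libraries in composition, and libraries 2, 3 and 4 of that group stood apart from all others. The 13 mtDNA-encoded genes, which code for respiratory chain subunits, took 12.46% of the counts in HOM DMSO replicate 1 and 20.68%, 21.29% and 21.92% in libraries 2 to 4, against 7.87% to 15.15% in the 12 other DMSO libraries. The sum of normalized counts was 22.94 M in replicate 1 and 32.02, 36.84 and 47.28 M in libraries 2 to 4, against 16.17 to 24.68 M elsewhere. Numbers of passing genes and of list members, and values of genes named by the rule, are therefore given also without libraries 2 to 4 where they use HOM in DMSO, a choice made after the data were seen. Tests of lists and values of single list members rest on all 4 libraries. The lone library is then assumed to vary like the other groups.

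**Figure D2:**
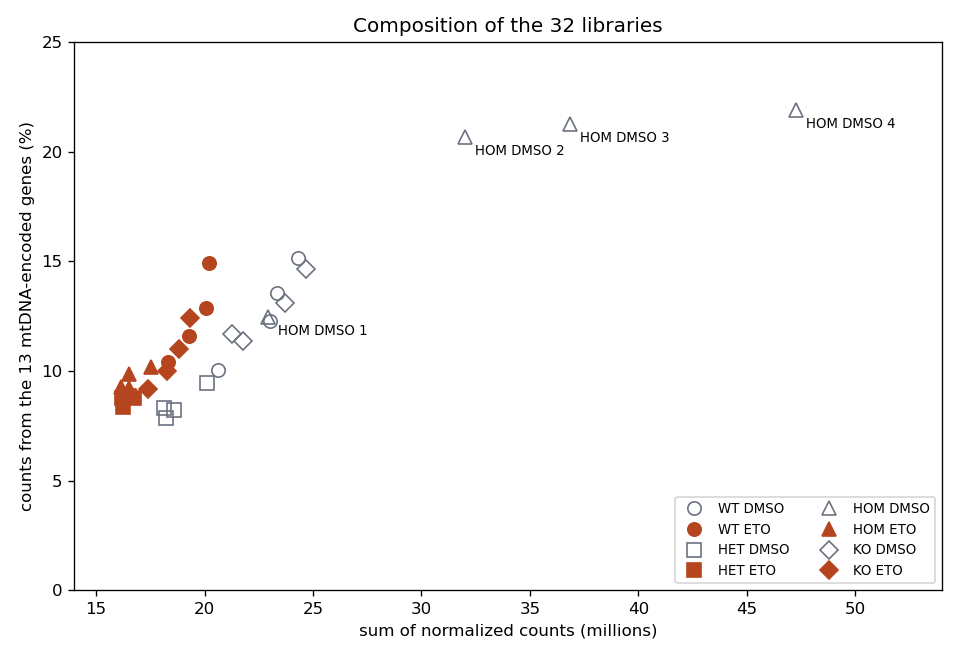
Percent of counts from the 13 mtDNA-encoded genes against the sum of normalized counts (M) in each of the 32 libraries, by genotype (marker shape) and treatment (colour). HOM DMSO libraries 2 to 4 lie at 20.68% to 21.92% and above 32 M.

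In wild-type cells etoposide raised p53 target genes and inflammatory genes and lowered genes of mitosis and DNA replication. CDKN1A, which encodes the cell cycle inhibitor p21, rose from 4651 ± 707 to 34110 ± 2040 normalized counts (SD, n = 4), a log2 fold change of 2.89 ± 0.14 (SE). GDF15, a secreted stress cytokine, rose from 243.3 ± 35.1 to 8205 ± 639. MDM2, the ubiquitin ligase that degrades p53, rose by 2.63 ± 0.24, and the pro-apoptotic genes BBC3 (PUMA) and BAX by 1.5 ± 0.1 and 0.83 ± 0.13. Their adjusted p-values were 2.65e-16 for CDKN1A, 5.44e-18 for GDF15, 2.93e-10 for MDM2, 4.47e-13 for BBC3 and 4.93e-06 for BAX. The largest rise by the naming rule was in TREM2, a receptor best known from myeloid cells, from 1.413 to 1210 normalized counts (log2 9.13 ± 0.28, adjusted p 1.68e-20). LCE1C and LCE1F, genes of the skin's cornified envelope, reached 707.1 and 359.5, from 3 recovered counts in all and from a mean of 1.004. The antimicrobial gene RNASE7 reached 319.3 from 3 recovered counts, and LGALS7B, which shares most of its sequence with LGALS7, was at least 78.8-fold higher. The chemokine CXCL14 fell by 4.19 ± 0.08 on the log2 scale (adjusted p 1.96e-25), from 13780 ± 939 to 752.9 ± 33.8. The stem cell factor SOX2 fell by 4.15 ± 0.16, the BMP and WNT antagonist SOSTDC1 by 4.17 ± 0.31, the kinase MAP2K6 by 4.67 ± 0.26 and the chemokine CCL24 fell by 4.38 ± 0.19.

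Of the 69 measured p53 targets, 57 rose and 1 fell in WT (58 and 1 adjusted over the list alone; camera adjusted p 1.9e-27). The fall was in STEAP3 (-1.23 ± 0.11), a ferrireductase, and PADI4, a peptidylarginine deiminase, rose by 5.54 ± 0.38. Of 46 G2 and mitosis genes, 37 fell (39 adjusted over the list alone; camera adjusted p 2.9e-20), among them PLK1 (-3.28 ± 0.19), a mitotic kinase. Of 45 S-phase genes, 33 fell and 2 rose (34 and 2 adjusted over the list alone; camera adjusted p 5.1e-15), with falls in POLA1 (-2.41 ± 0.23), a DNA polymerase subunit, and rises in CCNE2 (1.40 ± 0.39) and PCNA (0.63 ± 0.12). Of 31 homologous recombination and Fanconi genes, 14 fell and 1 rose (the same adjusted over the list alone; camera adjusted p 0.0024), but adjusted p = 0.51 with an estimated correlation. FANCC fell by 1.85 ± 0.08 and RAD50 rose by 1.20 ± 0.38. All 24 of the 27 NF-kB and cytokine genes that passed rose (24 adjusted over the list alone; camera adjusted p 7.1e-13), led by the metalloproteinase gene MMP3 (5.05 ± 0.29). Of 28 immediate-early genes, 18 rose and 3 fell (the same adjusted over the list alone; camera adjusted p 5.4e-09), and FOSB rose by 4.76 ± 0.23. Of 37 interferon-stimulated genes, 21 rose and 2 fell (the same adjusted over the list alone; camera adjusted p 1.2e-04), but adjusted p = 0.076 with an estimated correlation. The antiviral genes RSAD2 and IFIT2 rose by 4.76 ± 0.52 and 4.24 ± 0.36. Of 24 cholesterol synthesis genes, 11 fell and 1 rose (the same adjusted over the list alone; camera adjusted p 0.0057).

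In all, 3389 genes rose and 2501 fell in WT at adjusted p under 0.05 and 1.5-fold.

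Without p53, cells treated with etoposide still raised inflammatory genes and had weaker p53 target and cell cycle responses than WT. In KO, CDKN1A rose from 3063 ± 267 to 8875 ± 655 (1.54 ± 0.14, adjusted p 3.83e-10), and this rise was smaller than in WT (response difference -1.35 ± 0.20, adjusted p 7.20e-06). GDF15 rose from 33.59 ± 12.5 to 121.9 ± 14.3 (response difference -3.19 ± 0.29, adjusted p 2.26e-09), and MDM2 rose by 0.82 ± 0.24 (response difference -1.80 ± 0.34, adjusted p 2.32e-04). BBC3 and BAX did not pass in KO, with log2 fold changes of -0.10 and -0.08, and their responses differed from WT by -1.60 ± 0.14 (adjusted p 1.48e-09) and -0.91 ± 0.18 (adjusted p 5.17e-04). The chemokine CXCL8 rose in KO from 4.704 to 273.9 normalized counts, and in WT from 59.44 ± 55.6 to 164.3 ± 22.3. Its response was larger in KO (response difference 3.94 ± 0.97, adjusted p 3.97e-03). The WT libraries in DMSO ranged from 4.766 to 136.3, so the size of this difference rests on an uneven WT level in DMSO. FGF21, a metabolic hormone, rose in KO from 84.42 to 184.4 and fell in WT from 26.32 to 3.196. Its response difference was 3.81 ± 0.36 (adjusted p 4.60e-09). TREM2 and LGALS7B responded less: TREM2 had 1 recovered count in the KO libraries with etoposide and LGALS7B none, against means of 1210 and 226 in WT, so that the size of the difference rests on the pseudocount.

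Other large rises in KO were in ESM1, an endothelial proteoglycan (5.44 ± 0.37), the nicotinic receptor subunit CHRNA9 (4.87 ± 0.28), TMEM265 (4.62 ± 0.72) and TMEM52B (4.40 ± 0.37). Large falls were in PLCH1, a phospholipase C (-3.88 ± 0.29), CXCL14 (-3.73 ± 0.08), the receptor ROR1 (-3.72 ± 0.25), the adhesion receptor ADGRL3 (-3.39 ± 0.20) and the netrin receptor UNC5C (-3.22 ± 0.28). Of the 69 p53 targets, 25 rose and 5 fell in KO (25 and 6 adjusted over the list alone; camera adjusted p 0.0019), including GADD45A, a DNA damage gene (3.13 ± 0.20). All 24 of the 27 NF-kB and cytokine genes that passed rose (24 adjusted over the list alone; camera adjusted p 3.9e-14), among them the cytokine IL1A (4.69 ± 0.40). Of 37 interferon-stimulated genes, 24 rose and 1 fell (the same adjusted over the list alone; camera adjusted p 4.7e-06), and of 28 immediate-early genes, 18 rose and 2 fell (the same adjusted over the list alone; camera adjusted p 2e-06), though adjusted p = 0.094 with an estimated correlation for the latter. Of 20 replication histones, 17 fell (17 adjusted over the list alone; camera adjusted p 3.1e-10), with HIST1H2AC at -3.13 ± 0.20. In all, 3039 genes rose and 2444 fell in KO. Across genes, the KO and WT responses correlated with a Pearson r of 0.666 and a Spearman rho of 0.661, and 1922 genes rose and 1261 fell in both, where 612.2 and 363.3 were the numbers for independent lists; genes are not independent replicates.

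The difference between the KO and WT responses passed for 1196 genes on the higher and 1367 on the lower side. Of the 69 p53 targets, 48 responded less in KO (52 adjusted over the list alone; camera adjusted p 4.5e-31), and PADI4 differed by -3.90 ± 0.54. The response was higher in KO for 33 of 46 G2 and mitosis genes (36 adjusted over the list alone; camera adjusted p 1.8e-29) and for 41 of 45 S-phase genes (42 adjusted over the list alone; camera adjusted p 1.4e-38), with NUSAP1 at 2.40 ± 0.36 and GINS2 at 1.87 ± 0.22. It was higher for 14 of 31 homologous recombination and Fanconi genes (19 adjusted over the list alone; camera adjusted p 2.6e-10), but adjusted p = 0.086 with an estimated correlation. Of 27 NF-kB and cytokine genes 1 responded more and 3 less in KO (the same adjusted over the list alone; camera adjusted p 0.94).

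In untreated cells KO differed from WT in fewer genes, with p53 targets lower. GDF15 was lower in KO (-2.87 ± 0.20, adjusted p 1.91e-11), as were IGFBP4, which binds insulin-like growth factors (-9.22 ± 0.36, adjusted p 3.60e-17, 2.074 against 1696 normalized counts), and the peptide gene NMB (-6.16 ± 0.33). The mitochondrial carrier SLC25A20 was at 0 in KO and at least 19.2-fold lower, the protease ADAMTS7 was lower by -5.76 ± 0.29, and the homeobox gene DLX4 had 1 recovered count in KO against a mean of 58.3 in WT. LGR5, a stem cell receptor of the WNT pathway, was higher (2.68 ± 0.26, adjusted p 6.50e-09), as were NCKAP5 (3.03 ± 0.53), the epithelial factor EHF (3.02 ± 0.39) and the pseudogene FABP5P7 (4.47), which can take reads from its parent gene. Of 69 p53 targets, 20 were lower and 1 higher (21 and 1 adjusted over the list alone; camera adjusted p 1.8e-09). In all, 463 genes were higher and 941 lower, and 879 passed with the variance-stabilized values as deposited. CDKN1A was lower by -0.59 ± 0.14, a call that ended without WT DMSO 1 or 4 or KO DMSO 1 or 3 (-0.58 to -0.51), with quantile normalization (-0.54) and with the GC content and length trend removed (-0.57). MDM2, BBC3 and BAX did not pass, at -0.09, -0.57 and -0.57. BBC3 passed without WT DMSO 2 or KO DMSO 4 (-0.61 and -0.62), BAX without WT DMSO 2 or KO DMSO 2 or 4 (-0.67 to -0.59), and both with array weights (-0.63 and -0.66).

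With etoposide KO had lower p53 targets and higher cell cycle genes than WT. CDKN1A was lower by -1.94 ± 0.14 (adjusted p 2.61e-12), MDM2 by -1.89 ± 0.24 (adjusted p 1.92e-07), BBC3 by -2.17 ± 0.10 (adjusted p 1.98e-16), BAX by -1.48 ± 0.13 (adjusted p 1.81e-10) and GDF15 by -6.07 ± 0.20 (adjusted p 3.57e-19). TREM2 had 1 recovered count in the KO libraries and LCE1F 2, LGALS7B was at 0 and at least 87.5-fold lower, and LCE1C was lower by -7.44. FGF21 was higher (5.47 ± 0.25, 184.4 against 3.196), as were LGR5 (3.40 ± 0.26) and TNNT2, cardiac troponin T (2.97 ± 0.33). All 52 p53 targets that passed were lower (52 adjusted over the list alone; camera adjusted p 4.5e-31). Higher in KO were 43 of 46 G2 and mitosis genes (43 adjusted over the list alone; camera adjusted p 1.4e-26), 42 of 45 S-phase genes (42 adjusted over the list alone; camera adjusted p 4.5e-31) and 23 of 31 homologous recombination and Fanconi genes (23 adjusted over the list alone; camera adjusted p 4.1e-11, but adjusted p = 0.071 with an estimated correlation). Among them NUSAP1, a spindle protein, was higher by 2.93 ± 0.25 and CHAF1A, a chromatin assembly factor, by 1.83 ± 0.12. Of 27 matrix and osteoblast genes, 12 were lower and 1 higher (12 and 2 adjusted over the list alone; camera adjusted p 0.0015), but adjusted p = 0.25 with an estimated correlation; collagen COL6A3 was lower by -2.91 ± 0.11. In all, 1973 genes were higher and 2522 lower.

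Heterozygous cells showed the p53 target response to etoposide, with a smaller fall in replication genes than WT. CDKN1A rose from 1551 ± 154 to 17880 ± 988 (3.53 ± 0.14, adjusted p 3.61e-18), GDF15 from 22.79 ± 4.93 to 1657 ± 128 (6.15 ± 0.20, adjusted p 9.03e-20), MDM2 by 2.24 ± 0.24 (adjusted p 7.43e-09), BBC3 by 1.49 ± 0.10 (adjusted p 5.88e-13) and BAX by 0.87 ± 0.13 (adjusted p 2.69e-06). The adhesion gene NECTIN4 rose by 7.55 ± 0.27 to 962.1, TREM2 by 7.19 ± 0.28 to 273.7, ESM1 by 7.73 ± 0.37 to 309.2 and CHRNA9 by 6.48 ± 0.28 to 233.1. The protease inhibitor PI15 fell by 5.21 ± 0.44 on the log2 scale, the urea transporter SLC14A1 fell by 4.38 ± 0.19 and CXCL14 by 4.31 ± 0.08, the last from 80770 ± 6900.

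Of 69 p53 targets, 54 rose and 1 fell in HET (55 and 1 adjusted over the list alone; camera adjusted p 1.4e-26). All 24 of the 27 NF-kB and cytokine genes that passed rose (24 adjusted over the list alone; camera adjusted p 3.3e-14), with MMP3 at 6.03 ± 0.29, and of 28 immediate-early genes 20 rose and 1 fell (the same adjusted over the list alone; camera adjusted p 1.8e-11), with ATF3 at 4.12 ± 0.10. All 33 of the 46 G2 and mitosis genes that passed fell (35 adjusted over the list alone; camera adjusted p 4.4e-16), and of 45 S-phase genes 19 fell and 2 rose (the same adjusted over the list alone; camera adjusted p 1e-04). In all, 2937 genes rose and 2141 fell. Across genes the HET and WT responses correlated with a Pearson r of 0.822 and a Spearman rho of 0.805.

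The test of the difference between the HET and WT responses passed for 500 genes on the higher and 299 on the lower side (973 and 757 with array weights, 704 and 496 in a fit on the compared groups alone). S-phase genes responded higher in HET for 14 of 45 (19 adjusted over the list alone; camera adjusted p 1.8e-21), among them MCM3 of the replicative helicase (0.92 ± 0.10) and GINS2 (1.13 ± 0.22). G2 and mitosis genes did so for 7 of 46 (10 adjusted over the list alone; camera adjusted p 1.8e-09), but adjusted p = 0.05 with an estimated correlation, and MKI67 differed by 0.83. In a fit on the compared groups alone, 13 G2 and mitosis genes passed. All 7 of the 37 interferon-stimulated genes that passed responded less in HET (7 adjusted over the list alone, with 2 more on the higher side; camera adjusted p 0.0082), but adjusted p = 0.26 with an estimated correlation; IFIT2 differed by -3.83 ± 0.51 and RSAD2 by -3.48. Of the 69 p53 targets on the list, 4 responded more and 5 less (the same adjusted over the list alone; camera adjusted p 0.15), a balance that flipped to 5 and 4 with quantile normalization and to 4 and 2 with total-count scaling, among them TP53I3 (-1.07 ± 0.18), an oxidoreductase. Differences for MDM2, BBC3 and BAX did not pass, at -0.38, -0.02 and 0.04. The potassium channel KCNK10 rose in HET from 6.34 to 22.01 and fell in WT from 275.6 to 80.01. Its response difference was 3.45 ± 0.31 (adjusted p 9.73e-09). PI15 fell further in HET, from 680.4 to 16.96, than in WT, from 33.72 to 18.95. The PI15 response difference was -4.44 ± 0.62 (adjusted p 1.59e-05). LGALS7B rose less in HET, with 0 recovered counts in DMSO in both genotypes. The GDF15 difference (1.07 ± 0.29, adjusted p 2.26e-02) did not pass without WT DMSO 3, WT ETO 2 or HET DMSO 2 (0.91 to 1.02) or with quantile normalization (0.99), and was 0.02 (adjusted p 9.82e-01) with the variance-stabilized values as deposited. The CDKN1A difference (0.64 ± 0.20, adjusted p 4.81e-02) did not pass without any 1 of 14 libraries of the 16 (0.56 to 0.67), the exceptions being WT DMSO 2 and HET DMSO 3, nor without a filter on low values (0.64, adjusted p 8.39e-02) or with the GC content and length trend removed (0.57).

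In untreated cells HET differed from WT in many genes, with the cell cycle inhibitor gene CDKN2B higher and the binding protein gene IGFBP4 lower. CDKN2B, which encodes the cell cycle inhibitor p15, was higher by 5.87 ± 0.39 (adjusted p 6.76e-13, 746.2 against 12.05), and the matrix gene EPYC by 6.72 ± 0.55. The insulin-like factor IGFL3, the taste receptor chaperone RTP3 and the Notch target HEYL were higher by 4.68, 5.15 and 4.91. IGFBP4 was lower by -9.43, the acyltransferase GPAT2 by -6.54 ± 0.22, SPRY4, an inhibitor of growth factor signalling, by -6.44 ± 0.27 and the actin regulator FHOD3 by -6.23. HIST2H2AA3, a histone gene with a near-identical copy, was at 0 and at least 99.7-fold lower. CDKN1A was lower by -1.58 ± 0.14 (adjusted p 2.76e-10) and GDF15 by -3.38 ± 0.20 (adjusted p 9.48e-14). MDM2 (0.48), BBC3 (-0.40) and BAX (-0.22) did not pass, but MDM2 did without WT DMSO 2 (0.63, adjusted p 4.13e-02). Among 69 p53 targets, 18 were lower and 7 higher (the same adjusted over the list alone; camera adjusted p 0.08). The mtDNA-encoded genes were lower for 10 of 13 (10 adjusted over the list alone; camera adjusted p 0.0068), but adjusted p = 0.66 with an estimated correlation, and took 8.462 ± 0.674% of the counts in HET against 12.762 ± 2.146% in WT (SD, n = 4). Of 30 glycolysis and hypoxia genes, 14 were lower and 3 higher (the same adjusted over the list alone; camera adjusted p 0.0028), but adjusted p = 0.39 with an estimated correlation; the hypoxia marker CA9 was lower by -4.92. In all, 2710 genes were higher and 2759 lower. SPRY4 lies in a stretch of chromosome 5 (141121799 to 142698070) whose 50 tested genes had a median of -0.88, and CDKN1A in a stretch of chromosome 6 (36676460 to 42889925) with a median of 0.54.

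With etoposide HET had a part of the p53 targets lower than WT and replication genes higher. CDKN1A was lower by -0.93 ± 0.14 (adjusted p 5.41e-06; -0.54 and not passing with quantile normalization) and GDF15 by -2.31 ± 0.20 (adjusted p 5.78e-10), while MDM2, BBC3 and BAX did not pass, at 0.10, -0.42 and -0.18. CDKN1A and TREM2 lie in the chromosome 6 stretch, whose median was 0.51 with etoposide. Higher by the naming rule were FABP5P7 (5.71), RTP3 (5.32), CDKN2B (4.87 ± 0.39), EPYC (4.81) and FAM155B (4.79). Lower were IGFBP4 (-7.36), the sperm protein CABYR (-5.88 ± 0.32), the Notch coactivator MAML1 (-5.75 ± 0.82) and PCDHGB5, a protocadherin in the chromosome 5 stretch (-6.07 ± 0.43). CDC42EP5, in a stretch of chromosome 19 (53281559 to 58573575) that was also lower, was at 0 and at least 21.4-fold lower. On the p53 target list of 69, 22 were lower (22 adjusted over the list alone; camera adjusted p 3.9e-04). Higher were 19 of 45 S-phase genes (19 adjusted over the list alone; camera adjusted p 1.1e-09), 13 of 46 G2 and mitosis genes (14 adjusted over the list alone; camera adjusted p 1.5e-04) and 14 of 31 homologous recombination and Fanconi genes (14 adjusted over the list alone; camera adjusted p 1.2e-05). For G2 and mitosis adjusted p = 0.26 with an estimated correlation, and for homologous recombination adjusted p = 0.28 with an estimated correlation. In a fit on the compared groups alone, 22 G2 and mitosis genes passed. Of 37 interferon-stimulated genes, 16 were lower and 5 higher (the same adjusted over the list alone; camera adjusted p 0.0013), but adjusted p = 0.15 with an estimated correlation; IFIT2 was lower by -4.69 ± 0.36. In all, 1692 genes were higher and 2220 lower.

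Homozygous mutant cells raised CDKN1A and MDM2 with etoposide, and with etoposide most p53 targets were lower in HOM than in WT. CDKN1A rose from 3077 ± 947 to 7526 ± 407 (1.34 ± 0.14, adjusted p 2.00e-09; 1.90 without libraries 2 to 4), MDM2 by 2.35 ± 0.24 (adjusted p 1.52e-09; 1.23 without them) and GDF15 by 0.80 ± 0.20 (adjusted p 9.52e-04; 1.3 without them, but 0.16 with adjusted p 5.74e-01 with quantile normalization). BBC3 fell by 0.75 ± 0.10 on the log2 scale (adjusted p 1.65e-07; -0.70 without them), but its change was 0.26 with total-count scaling and 0.21 with the GC content and length trend removed. BAX fell by 0.70 ± 0.13 (adjusted p 2.17e-05), but had -0.20 without libraries 2 to 4, -0.52 without HOM DMSO 4, -0.08 with quantile normalization, 0.31 with total-count scaling and 0.10 with the trend removed. CXCL8 rose from 5.755 to 382.2 (6.28 ± 0.69, adjusted p 5.79e-09), the epimerase gene DSEL by 6.46 ± 1.05 and PIWIL2, a small RNA binding protein, by 5.94 ± 0.32. These had 4.91, 7.74 and 5.1 without libraries 2 to 4, and 5.27, 4.7 and 4.49 with a pseudocount of 5. CXCL14 fell by 4.35 ± 0.08 on the log2 scale (adjusted p 6.73e-26), BABAM2, a subunit of a BRCA1 complex, by 3.90 ± 0.18 and the kinesin KIF26B by 3.92 ± 0.54, with -4.40, -3.08 and -3.06 without libraries 2 to 4. In all, 6256 genes rose and 4788 fell, and 3519 rose and 2912 fell without libraries 2 to 4. The direction depends on the scaling: with total-count scaling 10595 rose and 1010 fell.

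Of the 69 p53 targets on the list, 41 rose and 10 fell in HOM (the same adjusted over the list alone; camera adjusted p 0.0028), and 31 rose and 5 fell without libraries 2 to 4 and 57 and 1 with total-count scaling. Of 37 interferon-stimulated genes, 30 rose and 1 fell (the same adjusted over the list alone; camera adjusted p 3.2e-06), with IFIT2 at 4.72 ± 0.36, and 29 rose and 1 fell without those libraries. All 17 of the 20 replication histones that passed fell (17 adjusted over the list alone; camera adjusted p 7.8e-05; 12 fell without those libraries, and 8 fell and 2 rose with total-count scaling). Of 27 NF-kB and cytokine genes, 17 rose and 3 fell (the same adjusted over the list alone; camera adjusted p 0.0027), and 20 rose and 2 fell without those libraries; PTGS2, the inducible cyclooxygenase, rose by 4.89 ± 0.29. Against the WT response, 4410 genes were higher and 4028 lower, 1509 and 1595 without libraries 2 to 4, and 8238 and 914 with total-count scaling. The response was lower in HOM for 37 of 69 p53 targets and higher for 4 (the same adjusted over the list alone; camera adjusted p 1.1e-09), lower for 47 without those libraries, and lower for 22 and higher for 13 with total-count scaling. It was higher for 39 of 46 G2 and mitosis genes and lower for 1 (the same adjusted over the list alone; camera adjusted p 8.2e-17; 37 without those libraries) and for 32 of 45 S-phase genes (32 adjusted over the list alone; camera adjusted p 1.3e-14; 39 without those libraries). The responses of CDKN1A, BBC3, BAX and GDF15 were lower than in WT by -1.55 (adjusted p 4.31e-07), -2.25 (adjusted p 1.97e-12), -1.53 (adjusted p 1.82e-07) and -4.28 (adjusted p 5.43e-12), and by -0.99, -2.20, -1.03 and -3.78 without libraries 2 to 4. MDM2 differed by -0.28 (adjusted p 4.96e-01), by -1.39 (adjusted p 4.90e-04) without them, by -0.77 with quantile normalization and by -0.71 with the GC content and length trend removed, where it passed each time.

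With etoposide HOM had lower p53 targets and higher cell cycle genes than WT. CDKN1A was lower by -2.18 ± 0.14 (adjusted p 1.94e-13), MDM2 by -1.54 (adjusted p 4.75e-06), BBC3 by -2.35 ± 0.10 (adjusted p 3.57e-17), BAX by -1.13 ± 0.13 (adjusted p 3.13e-08) and GDF15 by -5.80 ± 0.20 (adjusted p 1.23e-18). TREM2 was lower by -8.99 ± 0.28, LCE1F by -7.69, LCE1C by -7.50, LGALS7B by -6.59 and SERPINB5, the protease inhibitor maspin, by -7.05 ± 0.35. FGF21 was higher (4.44 ± 0.25, adjusted p 2.29e-14), as were the hormone receptor CCKAR (5.22), the receptor subunit GABRG1 (4.67 ± 0.70) and the peptide SPX (3.68 ± 0.22). All 56 p53 targets that passed were lower (56 adjusted over the list alone; camera adjusted p 1e-28). Higher were 43 of 46 G2 and mitosis genes (43 adjusted over the list alone; camera adjusted p 1.7e-24), 41 of 45 S-phase genes (41 adjusted over the list alone; camera adjusted p 9.7e-27) and 22 of 31 homologous recombination and Fanconi genes (23 adjusted over the list alone; camera adjusted p 9.3e-10, but adjusted p = 0.099 with an estimated correlation). Of 28 immediate-early genes, 14 were lower and 1 higher (14 and 2 adjusted over the list alone; camera adjusted p 1.4e-04), but adjusted p = 0.19 with an estimated correlation; CCN2, a matricellular growth factor, was lower by -1.90 ± 0.09. In the BCL2 family of apoptosis regulators, 7 of 16 were lower and 2 higher (the same adjusted over the list alone; camera adjusted p 0.33), with BMF higher by 2.50 and BCL2A1 lower by -2.63. In all, 2348 genes were higher and 2467 lower.

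In untreated cells HOM against WT had lower p53 targets and higher mtDNA-encoded genes, the latter in libraries 2 to 4. Among 69 p53 targets, 32 were lower and 5 higher (the same adjusted over the list alone; camera adjusted p 9.4e-05), 14 were lower without libraries 2 to 4, and 13 in a fit on the compared groups alone. All 13 mtDNA-encoded genes were higher (13 adjusted over the list alone; camera adjusted p 1.4e-04), but adjusted p = 0.55 with an estimated correlation. With total-count scaling 5 passed, with quantile normalization 1, and in a fit of limma on the compared groups alone 0, with 9 at an unadjusted p under 0.05. Without libraries 2 to 4, limma passed 0 of the 13, with 0 at an unadjusted p under 0.05. GLMP, a lysosomal membrane protein, was lower by -5.74 ± 0.19 (adjusted p 4.43e-19; -5.63 without libraries 2 to 4), and GTSF1, a germ cell factor, was at 0 and at least 28.9-fold lower. GDF15 was lower by -1.51 (adjusted p 1.99e-06; -2.02 without libraries 2 to 4). CDKN1A was lower by -0.63 ± 0.14 (adjusted p 3.52e-04; -1.19 without libraries 2 to 4), a call that ended without WT DMSO 1 (-0.55) or HOM DMSO 1 (-0.45) and in a fit on the compared groups alone (adjusted p 7.70e-02). MDM2 was lower by -1.27 (adjusted p 8.99e-05), but had -0.15 (adjusted p 8.03e-01) without libraries 2 to 4, and an adjusted p of 6.39e-02 in a fit on the compared groups alone. BBC3 (-0.10) and BAX (0.40) did not pass, but BBC3 was lower with total-count scaling (-0.66, adjusted p 1.05e-04) and with the GC content and length trend removed (-0.83, adjusted p 8.65e-06). In all, 3371 genes were higher and 4641 lower, and 173 and 591 without libraries 2 to 4. With total-count scaling these were 556 and 7708, in a fit on the compared groups alone 665 and 494, and with the trend removed 1410 and 2625.

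HOM against KO asks whether cells with both alleles changed still act on p53 targets, and with etoposide p53 targets mostly did not differ by enough to pass. None of the 5 targets passed between HOM and KO with etoposide: CDKN1A had a log2 fold change of -0.24 ± 0.14 (adjusted p 2.56e-01), MDM2 0.34 ± 0.24 (adjusted p 3.55e-01), BBC3 -0.17 ± 0.10 (adjusted p 2.50e-01), BAX 0.35 ± 0.13 (adjusted p 5.40e-02) and GDF15 0.27 ± 0.20 (adjusted p 4.11e-01). On the p53 target list of 69, 9 were higher and 1 lower (the same adjusted over the list alone; camera adjusted p 0.14), with the growth factor PGF at 1.79 ± 0.19, RRM2B, a ribonucleotide reductase subunit, at 1.38 ± 0.35 and the cytokine LIF at -0.92 ± 0.10. A call missed here does not show equal levels. The SE is pooled over all 8 groups, HOM in DMSO included. In a limma fit on the compared groups alone, 11 of the 69 passed and 42 had an unadjusted p under 0.05. The libraries of HOM and KO with etoposide did not overlap for BAX (1466 to 1626 against 1100 to 1261). Nor did they for CDKN1A (7160 to 8105 against 8159 to 9433). For MDM2, BBC3 and GDF15 they overlapped. In simulated data 83.6% of 1.5-fold changes reached an adjusted p under 0.05 in this comparison, and 100% of 2-fold changes passed. The simulation used the median spread over groups and changed only genes with a mean of at least 50, so these shares can be too high. The p53 target ABCA12, at 0.89 ± 0.35 (SE), did not pass.

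Interferon-stimulated genes and replication histones were higher in HOM than in KO with etoposide, and epithelial keratin KRT14 lower. Of 37 interferon-stimulated genes, 11 were higher (11 adjusted over the list alone; camera adjusted p 2.6e-06), among them IFITM1 (2.27 ± 0.27), a viral entry inhibitor, and OAS2 (1.82 ± 0.23), an RNA sensor. Of 20 replication histones, 9 were higher and 1 lower (12 and 1 adjusted over the list alone; camera adjusted p 3.6e-07), with HIST1H1C at 1.24 ± 0.15. Of 14 epithelial markers, 6 were lower (6 adjusted over the list alone; camera adjusted p 0.0024), but adjusted p = 0.19 with an estimated correlation; KRT14 was lower by -4.37 ± 0.18. In G2 and mitosis 1 of 46 genes was higher (1 adjusted over the list alone; camera adjusted p 0.83), and in S phase 3 of 45 were lower (3 adjusted over the list alone; camera adjusted p 0.089). By the naming rule, IGFBP4 was higher by 8.03 ± 0.36 (2153 against 9.019), DLX4 by 7.22 ± 0.30, NMB by 6.09 ± 0.33 and EPOP, a chromatin regulator, by 6.02 ± 0.35, and TCEAL7 averaged 115.6 against 2 recovered counts in KO. SERPINB5 was lower by -6.18 ± 0.35, the histone variant H2AFJ by -5.55 ± 0.26, the microfibril gene MFAP5 by -5.22 ± 0.34 and ZNF597 by -4.83 ± 0.47. In all, 1256 genes were higher and 785 lower.

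In untreated cells HOM and KO differed in many of these genes as well. IGFBP4 was higher in HOM by 10.31 ± 0.36, NMB by 7.63, the homeobox gene HOXB2 by 6.48 and ADAMTS7 by 6.42, and MFAP5 was lower by -6.78 ± 0.34 and H2AFJ by -5.05 ± 0.26. Without libraries 2 to 4 these 6 genes had 10.33, 6.92, 6.36, 5.76, -7.21 and -4.98. SERPINB5 was at 0 in HOM and at least 10.7-fold lower. BAX was higher by 0.97 (adjusted p 8.68e-07) and GDF15 by 1.36 (adjusted p 4.36e-06), and MDM2 was lower by -1.18 (adjusted p 1.32e-04). Without libraries 2 to 4 these had 0.47, 0.85 and -0.07, of which GDF15 passed. The BAX call also ended with quantile normalization (0.55), total-count scaling (0.41) and the GC content and length trend removed (0.31), which ended that of GDF15 too (0.57). CDKN1A did not pass (-0.04), but was lower without libraries 2 to 4 (-0.60), with total-count scaling (-0.60) and with the trend removed (-0.67). BBC3 did not pass (0.48). Of the 69 p53 targets on the list, 15 were higher and 20 lower (the same adjusted over the list alone; camera adjusted p 0.65), 5 and 6 without libraries 2 to 4, 9 and 14 in a fit on the compared groups alone, 3 and 35 with total-count scaling, and 4 and 17 with the trend removed. Replication histones were higher for 8 of 20 (8 adjusted over the list alone; camera adjusted p 0.011), but adjusted p = 0.25 with an estimated correlation; 5 were higher without libraries 2 to 4. In all, 3797 genes were higher and 4812 lower, and 736 and 721 without libraries 2 to 4. With total-count scaling these were 966 and 7537, in a fit on the compared groups alone 2661 and 2179, and with the trend removed 1894 and 2973.

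The HOM and KO responses to etoposide differed for the cytokine CSF2 (-3.00 ± 0.24, adjusted p 1.57e-09) and TRABD2B, a WNT protease (-2.49 ± 0.25, adjusted p 2.24e-07), with -3.05 and -1.94 without libraries 2 to 4. Interferon-stimulated genes responded more in HOM for 21 of 37 and less for 1 (22 and 2 adjusted over the list alone; camera adjusted p 5.1e-04), but adjusted p = 0.12 with an estimated correlation, and 4 did without libraries 2 to 4. Of 69 p53 targets, 27 responded more and 10 less (the same adjusted over the list alone; camera adjusted p 0.15), 6 and 2 without libraries 2 to 4, 17 and 7 in a fit on the compared groups alone, and 41 and 2 with total-count scaling. In all, 4099 genes were higher and 3245 lower, and 180 and 131 without libraries 2 to 4. These were 7953 and 239 with total-count scaling, 2148 and 2543 in a fit on the compared groups alone, 2564 and 2216 with quantile normalization, and 2248 and 1248 with the GC content and length trend removed. The difference for CDKN1A did not pass (-0.20, adjusted p 4.10e-01). Those for MDM2 (1.53, adjusted p 1.88e-03) and GDF15 (-1.09, adjusted p 4.78e-03) did not pass without libraries 2 to 4 (0.41 and -0.58), nor that for GDF15 with total-count scaling (-0.39) or the GC content and length trend removed (-0.32). Those for BBC3 and BAX (-0.65 and -0.62) did not pass without libraries 2 to 4 (-0.60 and -0.12) and were 0.05 and 0.09 with total-count scaling and 0.12 and 0.06 with the GC content and length trend removed.

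**Figure D3:**
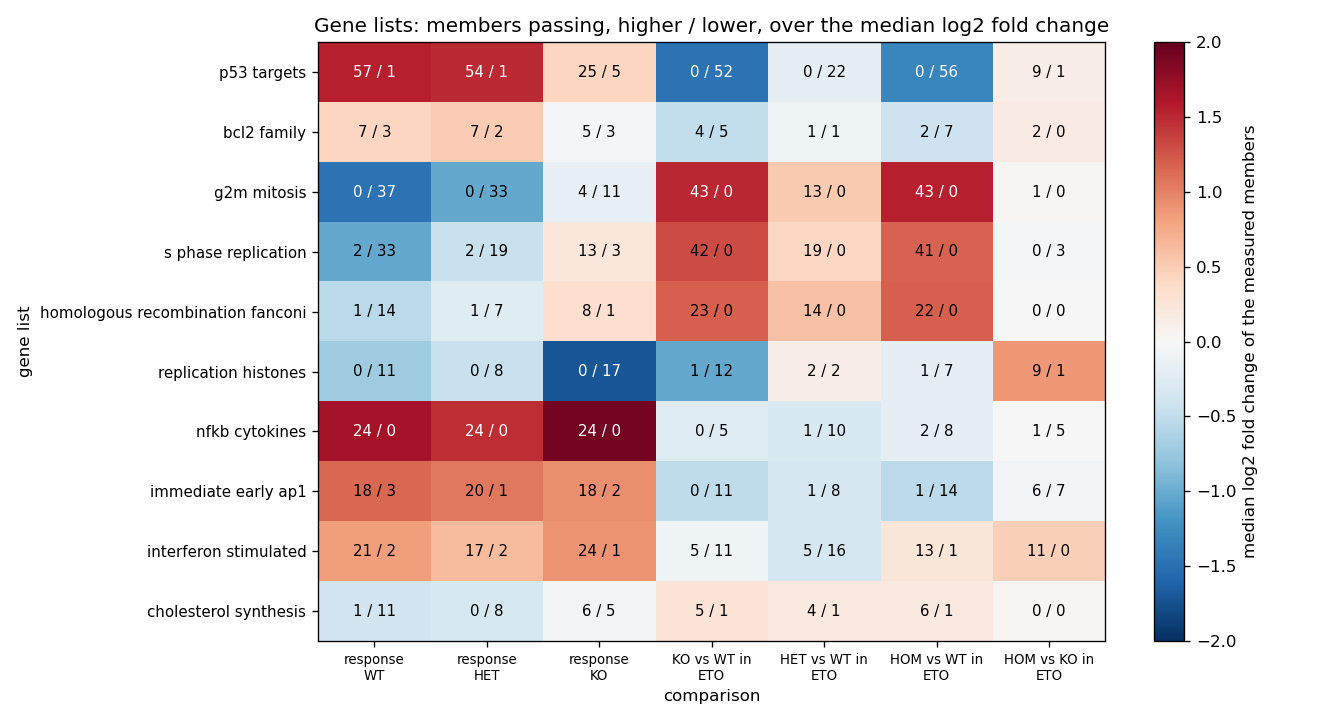
Gene lists against comparisons: each cell gives the members that passed, higher / lower, over the median log2 fold change of the measured members (colour). p53 targets read 57 / 1 in the WT response, 54 / 1 in HET and 25 / 5 in KO, and 9 / 1 in HOM against KO with etoposide.

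Genes that differed between genotypes were unevenly spread over the chromosomes. Of the 260 tested genes of chromosome 13, 112 were lower and 12 higher in HOM than in WT with etoposide, and 114 were lower and 5 higher in HOM than in KO. In KO against WT with etoposide, 33 were lower and 30 higher.

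**Figure D4:**
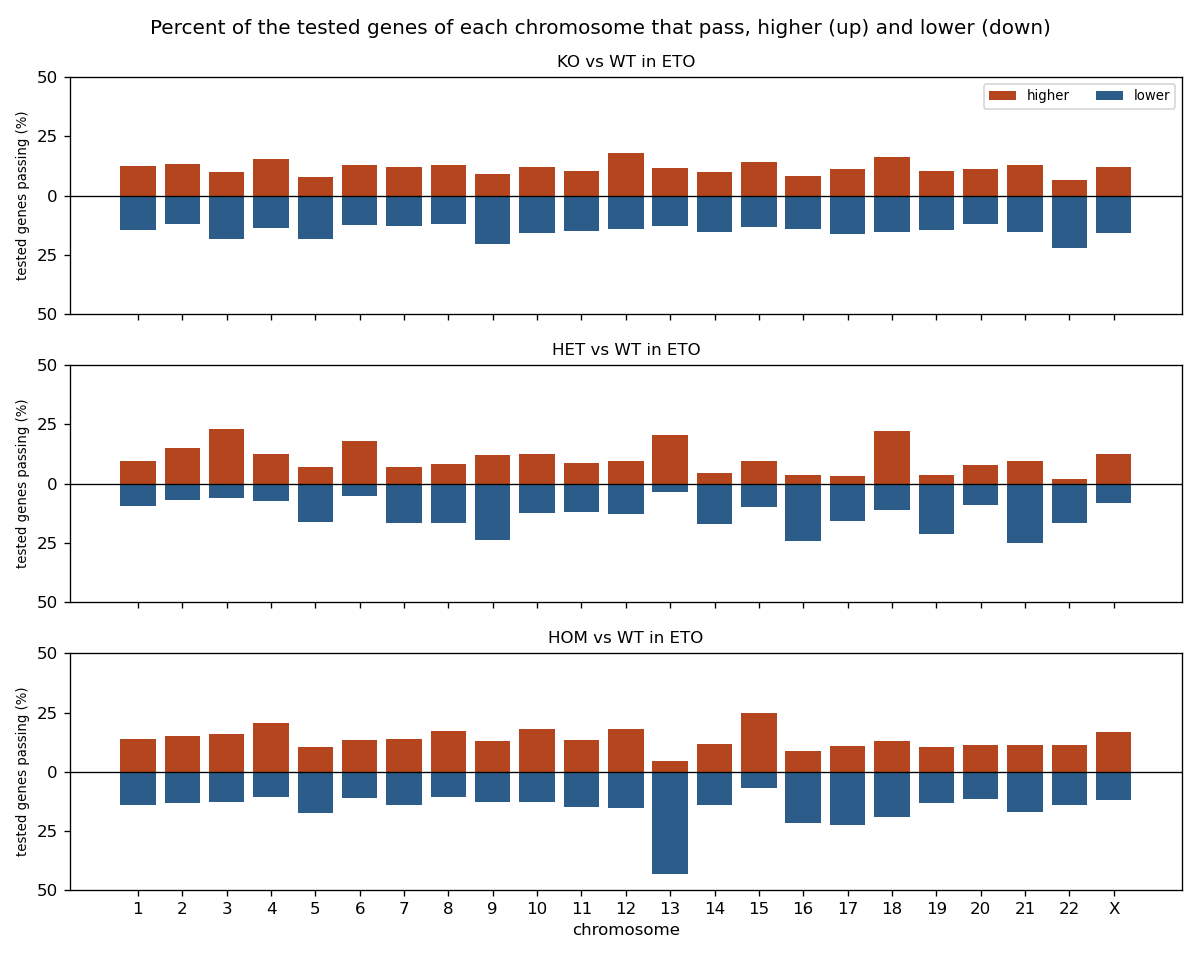
Percent of the tested genes of each chromosome that were higher (up) or lower (down) than in WT with etoposide, for KO, HET and HOM. Chromosome 13 in HOM has 112 of its 260 tested genes on the lower side.

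The authors' deposited tables, read at the same thresholds, passed 4688 genes for KO against WT with etoposide (4413 shared with the limma test), 5083 for HOM against WT (4765 shared) and 2280 for HOM against KO (1995 shared). In DMSO they passed 1448 for KO against WT (1310 shared), 7235 for HOM against WT (7000 shared) and 7957 for HOM against KO (7716 shared). No shared gene had the opposite direction.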

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

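Tests chosen after the result was seen were those of scaling and of the genotype in the HOM DMSO libraries, the comparison of these libraries with the DMSO libraries of other genotypes, the splits that kept these libraries together, the regroupings without the genotype difference common to both treatments, the count of chromosome windows no longer outside the shuffled range, and the correlation of chromosome window medians after the GC content and length trend was removed.

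Some single libraries stood far from the other 3 of their group, by a gap above Dixon's 95% critical value, in 10 of 196 groups of values examined, where chance gives about 1 in 20. The recovered total was 22.98 M counts in HET DMSO replicate 3 (20.83 to 21.01 M in the others) and 8.05 M in HET ETO replicate 2 (19.2 to 20.62 M). The number of genes with a count was 20425 in KO ETO replicate 1 (22144 to 22305 in the others) and 20819 in HET ETO replicate 2 (23083 to 23340). MDM2 was at 313.41 normalized counts in KO DMSO replicate 1 (251.66 to 260.58). In the WT ETO libraries, LCE1F was at 323.12 in replicate 2 (368.4 to 374.57), SERPINB5 at 436.52 in replicate 2 (355.25 to 368.4) and CDC42EP5 at 129.15 in replicate 4 (45.157 to 58.352). EPOP was at 304.42 in HOM ETO replicate 4 (259.23 to 265.92). The share of counts from mtDNA-encoded genes was 12.46% in HOM DMSO replicate 1, against 20.68% to 21.92% in the others of its group.

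HOM DMSO libraries 2 to 4 stood apart from all other libraries in composition. The tables argue against the scaling of the deposited values as the whole cause, since 1 factor per library leaves shares as they are, and mtDNA-encoded genes took at least 20.68% of the counts in libraries 2 to 4, against at most 15.15% in the 12 other DMSO libraries. Scaling as a part of the cause stays open. Libraries of another genotype under this label stay open by the bound set in advance, since libraries 2 to 4 had 75% to 80%. That bound was over 80% of 20 genes that separate HOM with etoposide lying nearest the HOM mean. Replicate 1 at 80% did not meet it either, so the bound cannot decide. The 12 DMSO libraries of other genotypes had 5% to 30%, and libraries 2 to 4 were far nearer to HOM. These values argue against libraries 2 to 4 being WT, HET or KO as a whole. GLMP was at most 8.962 normalized counts in the 4 HOM DMSO libraries and at least 123.6 in every library of the other genotypes. It was named from these same DMSO libraries, so its gap from WT and KO in DMSO follows from that choice. With etoposide HOM had 5.952 to 9.497. H2AFJ, named also in HOM against KO with etoposide, was at most 23.36 in HOM DMSO and at least 215 in the other genotypes. GC content and transcript length explained 26.9% to 49.4% of the variance over genes of the difference between these libraries and replicate 1, and up to 28.7% of the difference of a library from its group elsewhere, so a bias of this kind may take part and stays open. An effect of the A347D/A347D genotype also stays open, because replicate 1 at 12.46% is 1 library and excludes nothing.

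Genes that differed between genotypes lay side by side on the chromosomes. Of 323 windows of 50 neighbouring genes, 2 had a median beyond all 1000 shuffled gene orders in both treatments for KO against WT, 32 for HET against WT, 4 for HOM against WT and 7 for HOM against KO. With the GC content and length trend removed there were 1, 22, 7 and 11, of which 1, 8, 4 and 7 were among the windows before. For these windows the values argue against that trend as the whole cause. For the 1 other window for KO and the 24 others for HET it stays open, since they are known only by their return to the shuffled range. A candidate explanation for KO and HET is a difference in copy number or regional silencing between the cell lines, since window medians in DMSO and etoposide correlated across windows with r of 0.77 and 0.96, above the highest shuffled values of 0.45 and 0.73. For HOM this stays open: the r of -0.19 and 0.17 against WT and KO met the bound set in advance against it, but the DMSO medians carry the GC content trend of libraries 2 to 4, and r was 0.61 and 0.67 once it was removed. With the trend removed, neighbouring windows of chromosome 13 (27920020 to 113490952) were lower in HOM than in WT in both treatments. Their medians were -1.18 to -0.86 in DMSO and -1.04 to -0.51 with etoposide, the latter without libraries 2 to 4.

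The responses to etoposide differed between genotypes by the test of the difference itself. Between KO and WT 2563 genes passed, between HET and WT 799, between HOM and WT 8438 and between HOM and KO 7344. Of 100 regroupings of the libraries within each treatment, 2, 4, 1 and 1 gave as many, with 3252, 5354, 5890 and 7019 as the highest others. These say nothing about chance, because such a regrouping carries the genotype difference of both treatments into the response, and the 5354, several times the real number, point to this structure of the samples. With the genotype difference common to both treatments removed, 1 of 100 regroupings, the real one, gave as many in each of the 4. The highest others were 931, 115, 3759 and 14. A share of 1 in 100 is the lowest that these regroupings can give. It argues against an arbitrary grouping of the plates, and does not part genotype from cell line. For HOM this does not part the genotype from libraries 2 to 4, which 10 of the other regroupings kept together (up to 3759 and 14). Without these libraries 3104 genes passed between HOM and WT and 311 between HOM and KO, and no regroupings were run.

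For the comparisons of 2 groups, 1 of the 35 splits, the real one, gave as many genes in each of the 12. A share of 1 in 35 is the lowest that these splits can give, and it was not adjusted over the 12 comparisons. For the 9 that do not use HOM in DMSO it argues against an arbitrary grouping of the plates. It does not part genotype from cell line. For the other 3 the real split also gave the most, but the number followed libraries 2 to 4. The 4 other splits that kept these together gave 8327 to 9356 in the HOM response, 5784 to 7839 for HOM against WT and 6599 to 8074 for HOM against KO. The 30 that parted them gave at most 4806, 1682 and 31. This structure of the samples does not part the genotype from these libraries. The highest other split gave 1 gene in the WT response (5890 in the real one), 5 in HET (5078), 9356 in HOM (11044) and 3 in KO (5483). In DMSO it gave 14 for KO against WT (1404), 2525 for HET against WT (5469), 7839 for HOM against WT (8012) and 8074 for HOM against KO (8609). With etoposide it gave 1 for KO against WT (4495), 1 for HET against WT (3912), 2 for HOM against WT (4815) and 1 for HOM against KO (2041). Of the 9 without HOM in DMSO, only HET against WT in DMSO had another split above 14, with 2525. Its libraries thus hold a structure besides the genotype, whose cause was not tested here.

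Named genes whose response was higher in KO than in WT were CXCL8 (3.94), FGF21 (3.81) and CT45A3 (3.03). CT45A3 shares its sequence with near copies, and its call ended in 14 of 16 fits without 1 library (2.82 to 3.10), the exceptions being WT DMSO 1 and KO ETO 3. It also ended with a pseudocount of 5 (1.07), without a filter (3.03), with quantile normalization (2.45) and with the deposited values (0.49). Lower in KO were TREM2 (-8.91), LGALS7B (-7.81), AC005832.4 (-7.69), CDKN1A (-1.35), MDM2 (-1.80), BBC3 (-1.60), BAX (-0.91) and GDF15 (-3.19). Groups at or near 0 counts make the size for TREM2, LGALS7B and AC005832.4 depend on the pseudocount, and a pseudocount of 5 gave -7.52, -5.51 and -4.89. In HET against WT, HSD17B8 (5.54), DSEL (5.08), KCNK10 (3.45), CDKN1A (0.64) and GDF15 (1.07) were higher, and LGALS7B (-4.55), PI15 (-4.44) and LGALS7 (-4.20) lower. With a pseudocount of 5, LGALS7B had -4.07, LGALS7 -3.45 and DSEL 3.76. The HSD17B8 call ended without WT DMSO 3 or 4, WT ETO 1 or 2, or HET DMSO 2 or 4 (4.79 to 5.30), and that of GDF15 without WT DMSO 3, WT ETO 2 or HET DMSO 2 (0.91 to 1.02), with quantile normalization (0.99) and with the deposited values (0.02). The DSEL call ended in 12 of 16 fits without 1 library (4.36 to 5.15), the exceptions being WT DMSO 4, WT ETO 3 and 4 and HET DMSO 2, and that of CDKN1A in 14 (0.56 to 0.67), the exceptions being WT DMSO 2 and HET DMSO 3. Both calls ended without a filter on low values.

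In HOM against WT, DSEL (5.30), CCKAR (5.06), and COMMD3-BMI1 (4.15), a readthrough of neighbouring genes, were higher. Lower were TREM2 (-7.88), LCE1F (-7.44), LCE1C (-6.86), CDKN1A (-1.55), BBC3 (-2.25), BAX (-1.53) and GDF15 (-4.28). Without libraries 2 to 4, COMMD3-BMI1 had 1.33 (adjusted p 6.37e-01), DSEL 6.59, CCKAR 3.58, LCE1F -6.94, CDKN1A -0.99 and BAX -1.03. With a pseudocount of 5, TREM2 had -7.22, LCE1F -5.87, LCE1C -6.27, CCKAR 3.29 and DSEL 3.62, since some of their groups lie near 0. DSEL averaged 8.495 normalized counts in HOM DMSO, with a range of 0 to 33.98. In HOM against KO, DSEL (5.13), TCEAL7 (4.54) and MDM2 (1.53) were higher. With a pseudocount of 5, DSEL had 3.42 and TCEAL7 3.72. Lower were CSF2 (-3.00), AC138696.1 (-2.62), TRABD2B (-2.49), BBC3 (-0.65), BAX (-0.62) and GDF15 (-1.09). Without libraries 2 to 4, AC138696.1 had -2.04, MDM2 0.41, BBC3 -0.60, BAX -0.12 and GDF15 -0.58, and none of these 5 passed, while DSEL had 6.41, TCEAL7 3.18, CSF2 -3.05 and TRABD2B -1.94. The AC138696.1 call ended in 11 of 16 fits without 1 library (-2.70 to -1.36), the lowest in size without KO DMSO 2 and the others without KO DMSO 3, any KO ETO library, HOM DMSO 3 or 4, or HOM ETO 1, 2 or 3. That of GDF15 ended with total-count scaling (-0.39) and with the GC content and length trend removed (-0.32). The BAX call ended also without KO DMSO 1 (-0.58) or HOM DMSO 4 (-0.44).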

How the results depend on the processing

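Total-count scaling, leaving out HOM DMSO libraries 2 to 4, array weights, voom, the variance-stabilized values as deposited and removal of the GC content and length trend were chosen after the data were seen. The quasi-likelihood test on recovered counts was not run.

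Numbers of passing genes that moved by over 1.5 times mostly involved HOM in DMSO, and the cause was not tested unless given. Without HOM DMSO libraries 2 to 4, which leaves fewer samples, 6431 genes passed in the HOM response, 764 for HOM against WT and 1457 for HOM against KO in DMSO, and 3104 and 311 for the differences of the HOM response from WT and KO. Fits on the compared groups alone gave 1159 for HOM against WT and 4840 for HOM against KO in DMSO, 4691 for the HOM and KO response difference and 1200 for HET and WT. With the GC content and length trend removed there were 4035, 4867 and 3496 for the first 3 of these. Quantile normalization gave 4780 for the HOM and KO response difference, array weights gave 1730 for the HET and WT response difference, and the deposited values gave 879 for KO against WT in DMSO.

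Without 1 library at a time no number moved by over 1.5 times. For HOM against WT in DMSO it ranged from 5419 without HOM DMSO 4 to 9715 without HOM DMSO 1, for HOM against KO in DMSO from 6498 to 10005, for KO against WT in DMSO from 1209 to 1348 and for the HET and WT response difference from 673 to 785. Over all such fits, 2214 calls of named genes were the same, 83 weaker and 7 stronger.

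BBC3 and BAX in HOM reversed their direction. In the HOM response, total-count scaling gave 0.26 for BBC3 and 0.31 for BAX, and removal of the GC content and length trend 0.21 and 0.10. In the difference between the HOM and KO responses these were 0.05 and 0.09, then 0.12 and 0.06. With total-count scaling the median log2 fold change of all genes was 1.133 in the HOM response, against 0.159 with the deposited scaling. It was 0.277 in the WT response, 0.202 in HET and 0.347 in KO, against 0.054, 0.013 and 0.046. For HOM against WT in DMSO it was -0.58, against -0.066. Total-count scaling applies 1 factor per library to all genes. Its reversals are thus part of a shift of all genes, and not particular to BBC3 and BAX. The cause of the reversals with the trend removed was not tested.

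With voom, a replicate block, rescaling by the median of ratios and the stricter filter, all 240 calls of named genes were the same. The replicate numbers did not pair the samples. In simulated data 83.6% of 1.5-fold changes reached the adjusted p for HOM against KO with etoposide and 47.8% passed, since the fold threshold equals the simulated fold. For the difference between the HOM and WT responses 47.8% reached the adjusted p, so that the spread between libraries limits small changes there. The simulation used the median spread over groups and not the larger spread of HOM in DMSO, so this share can be too high.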

Other observations

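No test in this part was chosen after its result was seen, apart from the values with total-count scaling and without HOM DMSO libraries 2 to 4.

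Further lists were counted in the WT response. Of 14 epithelial markers 9 rose and 1 fell (9 and 3 adjusted over the list alone; camera adjusted p 0.077), and 3 rose and 1 fell with the stricter filter, with GRHL2 at 3.22 and KRT14 at -2.38. Of 16 BCL2 family genes 7 rose and 3 fell (the same adjusted over the list alone; camera adjusted p 0.24), with BCL2A1 at 5.56 and BMF at -3.71. All 11 of the 20 replication histones that passed fell (11 adjusted over the list alone; camera adjusted p 6.1e-05). Of 30 glycolysis and hypoxia genes 8 rose and 8 fell, and 7 rose and 2 fell with quantile normalization (camera adjusted p 0.88), and of 27 matrix and osteoblast genes 3 rose and 6 fell (camera adjusted p 0.43), the same for both adjusted over the list alone. Of 39 ATF4 stress genes 9 rose and 9 fell (the same adjusted over the list alone; camera adjusted p 0.76), with ATF3 at 3.64 and PHGDH, of serine synthesis, at -2.13. Of 20 unfolded protein response genes 3 rose and 1 fell (the same adjusted over the list alone; camera adjusted p 0.92), with DNAJB9 at 1.5. Of 23 NRF2 targets 3 rose and 6 fell, and 6 rose and 3 fell with total-count scaling (camera adjusted p 0.65), with AKR1B10 at 4.08. Of 16 mitochondrial chaperones and proteases 1 rose and 2 fell (camera adjusted p 0.98), and of 29 outer membrane and dynamics genes 3 rose (camera adjusted p 0.87), among them BNIP3, a mitophagy receptor (0.85). Of 58 nuclear oxidative phosphorylation genes 7 fell and 1 rose (camera adjusted p 0.012), but adjusted p = 0.67 with an estimated correlation. For these last 4 lists the numbers were the same adjusted over the list alone.

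In the HET response 5 of 50 cytosolic ribosomal protein genes fell (5 adjusted over the list alone; camera adjusted p 3.4e-04), but adjusted p = 0.63 with an estimated correlation. In the HOM response 39 fell and 1 rose (the same adjusted over the list alone; camera adjusted p 8e-08), but adjusted p = 0.49 with an estimated correlation; 26 fell without HOM DMSO libraries 2 to 4, and with quantile normalization the direction flipped, to 14 higher and 2 lower.

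The cells expressed 14 of 20 epithelial markers and 9 of 18 blood cell markers at the level tested. Of the 9 blood cell markers, 4 rose and 2 fell in the WT response (the same adjusted over the list alone; camera adjusted p 0.6), with CD68 at 1.86 and CD34 at -1.98. The keratin KRT17 had a median of 13130 normalized counts over the libraries, KRT14 521.3, CD34 352.3, CD68 170.8, the leukocyte gene PTPRC 10.34 and the globin gene HBB 0.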
